A study of Homo sapiens with 24 samples.

How the data were processed

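RNA was measured in 24 libraries of MOLM13 cells with a stable hairpin. They formed 8 groups of 3, taken from the labels of each sample: scr and shCDK9 cells at 48 h and scr and shDHODH cells at 96 h, each with DMSO or 8 nM gilteritinib. Libraries were made with a template-switching kit and tagmentation, per the labels' protocols, and no molecular identifiers are mentioned. Per the submitters' processing notes, the tools were CASAVA 1.8.2, HISAT2 2.0.6 (also given as 2), Subread, featureCounts and DESeq2 with the GRCh38 build. The role and order of each tool, the gene annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here.

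The deposited table gives 1 signal value per gene line and library, and the authors' values are read counts divided by 1 factor per library. It holds 63299 lines for 48482 names. All values (100%) were whole multiples of the value of 1 read in their library, within a tolerance of 1e-06, and that value was 0.783 to 1.40, so whole reads were recovered for each library. They summed to 14.3 M to 20.1 M. Lines with the same name were summed, which concerned 4377 names with 6.33% of reads; for these genes, and for paralogs, reads may be split or shared between copies. Names were matched to symbols by name, and 32605 had one. Positions, lengths and GC content came from GENCODE 29, which held a length for 86.8% of the genes tested at 48 h.

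Because the deposited values are normalised, limma 3.58.1 in R 4.3.3 was run on log2 of the value plus 1 (eBayes with trend and robust), with 1 mean per group and the 12 libraries of a time point, or all 24 for the comparison of times. Genes were kept by filterByExpr of edgeR 4.0.16 on the recovered reads (minimum count 10, minimum total 15). The log scale with 1 added understates the change of genes with few reads. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, and genes under 0.05 are called passing; ± after a log2 value is its SE and after a read count the SD. The plan assumed raw counts and edgeR with TMM factors. That test was run as an alternative on the recovered reads and passed 5134 genes for gilteritinib in scr cells at 48 h and 5924 at 96 h. The 13 comparisons were the drug in each line, each hairpin with and without drug, the difference of drug responses between the lines, drug and hairpin together against scr cells with DMSO, and the drug response at 96 h against 48 h in scr cells. The shCDK9 and shDHODH lines were sampled at different times and are never compared directly.

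The plan, the gene lists, the rule for named genes and most alternatives were set before the data were examined. The 32 lists came from general knowledge of FLT3 signalling, CDK9, DHODH and myeloid cells, and 4 of them are markers of other cell types. Some genes stand in several lists, so calls of such lists are not independent. Lists with at least 5 genes tested were compared with all other genes by camera with a preset correlation of 0.01, adjusted across the lists of a comparison. Camera with an estimated correlation, fry, and TMM, RLE and upper-quartile factors were alternatives; fry asks whether a list moves one way and does not compare it with other genes. No passing list had a median of the other sign under those 3 factors. The rule for named genes takes CDK9, DHODH and FLT3, and genes that pass with a mean CPM of at least 5 and no overlap between the groups (10% of splits of 3 against 3 have none by chance): the 8 with the largest rise and the 8 with the largest fall for the drug in scr cells and for each hairpin with DMSO, 5 and 5 for the drug in the hairpin lines and for the differences between lines, and 3 and 3 elsewhere. From each passing list it takes up to 4 genes with the smallest p that moved with the list; not each gene it gives is printed. The differences and the comparison of times had no overlap rule.

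The steps were tested on simulated counts with 100 genes changed by each size. All other genes had the same mean in all groups, and each gene had the same dispersion in all groups. The real data differ in both, so the shares below are not the sensitivity of the real comparisons. For gilteritinib in scr cells at 48 h (14709 genes) 72% of changes of log2 1 and 6% of changes of 0.5 were recovered, with 3.70% of calls false. At 96 h (14314 genes) the shares were 96%, 69% and 6.78%, and for the difference between shDHODH and scr cells (14324 genes) 93%, 54% and 5.16%.

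Alternatives set beforehand were edgeR with RLE or upper-quartile factors, DESeq2 1.42.0 with its own size factors, limma voom with quality weights, no filter or a filter of 1 CPM in 6 libraries, all 24 libraries or only the 6 compared, the replicate number as a block, and each library left out in turn. EdgeR with TMM, the planned test, became an alternative once the unit was known. Alternatives added after the data were seen were TMM factors in limma, 0.5 or 5 added before the log, only names with 1 line, the gene length trend of each library removed by a spline with 5 degrees of freedom, and replicates 1 and 2 of scr cells with gilteritinib at 48 h left out. Replicate numbers did not pair the samples: with group means removed, libraries of different groups with the same number had correlations across genes of -0.352 to 0.179 at 48 h and -0.0702 to 0.0497 at 96 h, and 3 and 1 of 12 libraries matched their own number best.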

Results

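Messenger RNA levels were measured by RNA sequencing in MOLM13, a human acute myeloid leukaemia cell line that carries an internal tandem duplication of FLT3 and a KMT2A rearrangement. The cells stably expressed a scrambled short hairpin RNA (scr), a hairpin against CDK9 (shCDK9) or a hairpin against DHODH (shDHODH). CDK9 is the kinase of P-TEFb, the complex that releases paused RNA polymerase II, and DHODH is the mitochondrial enzyme that makes orotate in de novo pyrimidine synthesis. The cells received DMSO, the solvent, or 8 nM gilteritinib, an inhibitor of the FLT3 receptor tyrosine kinase, at a dose that the series calls sublethal. The series asks whether lowering either gene changes the transcriptome in a way that goes with greater sensitivity to the drug. The 24 libraries formed 8 groups of 3. At 48 h there were 12 libraries, from scr and shCDK9 cells with and without gilteritinib, and at 96 h there were 12, from scr and shDHODH cells. Libraries held 14.3 M to 20.1 M assigned reads. The labels do not say whether the 3 replicates of a group were separate cultures, so the p-values measure only the spread between these samples.

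**Figure D1:**
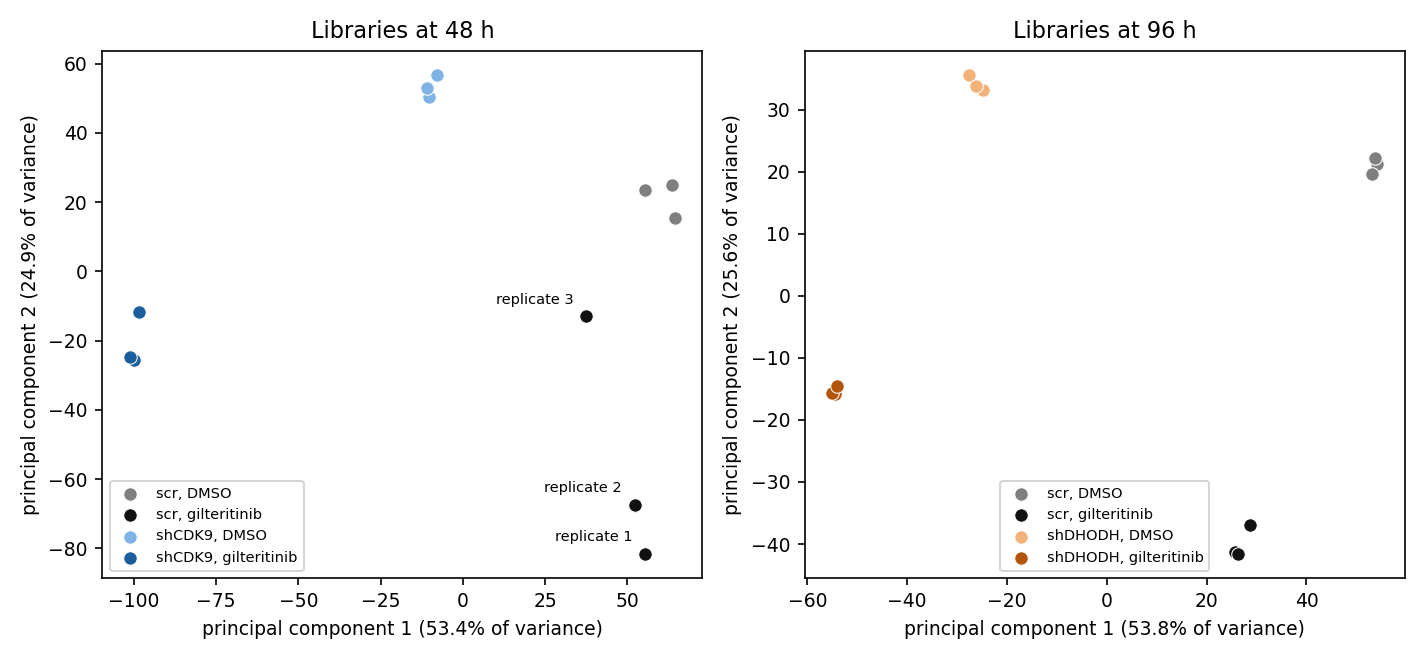
Principal components of the 12 libraries at 48 h and the 12 at 96 h, 1 point per library and 1 colour per group; each axis gives its share of variance. At 48 h replicates 1 and 2 of scr cells with gilteritinib lay at -81.6 and -67.5 on component 2 and replicate 3 at -13.0, while at 96 h each group was tight.

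Replicates of 7 groups were close to each other, with a median SD of log2 normalised counts of 0.0901 to 0.129, and scr cells with gilteritinib at 48 h were not, with 0.355. In that group replicates 1 and 2 stood apart from replicate 3. The correlation across genes was 0.99 between replicates 1 and 2, 0.952 between 1 and 3 and 0.966 between 2 and 3, where genes are not independent replicates. Genes with names of ribosomal proteins took 23.2% and 21.4% of reads in replicates 1 and 2 and 13.7% in replicate 3, against 11.1% to 17.5% in the other 21 libraries. Each comparison that uses this group was therefore also made with replicates 1 and 2 left out. This leaves replicate 3 as the only library of its group, so such values rest on 1 library, which is assumed to vary like the other groups. Mitochondrially encoded genes took 5.03% ± 0.0745 of reads in shCDK9 cells with DMSO and 2.91% ± 0.384 in scr cells at the same time (SD, n = 3).

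CDK9 and DHODH transcripts were lower in the lines that carry the matching hairpin, with and without gilteritinib. In GRCh38 the CDK9 gene (ENSG00000136807) lies on chromosome 9 from 127785679 to 127790787 on the plus strand, DHODH on chromosome 16 from 72008588 to 72027664 on the plus strand, and FLT3 on chromosome 13 from 28003274 to 28100592 on the minus strand. All 3 are annotated as protein-coding, and the table gives whole genes, so no exon or untranslated region was measured apart. With DMSO at 48 h the CDK9 normalised read count was 1127 ± 36.6 in scr cells and 532 ± 38.0 in shCDK9 cells (SD, n = 3), a log2 fold change of -1.08 ± 0.09, adjusted p = 6.0e-06 (limma, Benjamini-Hochberg). With gilteritinib it was 1274 ± 108 and 667 ± 30, a log2 fold change of -0.93 ± 0.09, adjusted p = 5.5e-06. The DHODH normalised read count with DMSO at 96 h was 470 ± 25.4 in scr cells and 249 ± 7.26 in shDHODH cells, -0.91 ± 0.08, adjusted p = 3.0e-11, and with gilteritinib 432 ± 13.6 and 262 ± 27.2, -0.72 ± 0.08, adjusted p = 4.3e-09. For the gene not targeted, CDK9 at 96 h was 1194 ± 81.4 and 1181 ± 64.2 in scr cells with DMSO and gilteritinib and 985 ± 41.7 and 895 ± 23 in shDHODH cells, and DHODH at 48 h was 483 ± 39.4 and 623 ± 143 in scr cells and 516 ± 17.4 and 305 ± 35.9 in shCDK9 cells. CDK9 was also lower in shDHODH cells with DMSO at -0.28 ± 0.06, adjusted p = 2.2e-04, and DHODH fell by 0.76 ± 0.16 with gilteritinib in shCDK9 cells (adjusted p = 0.0016), where scr cells gave 0.34 ± 0.16, adjusted p = 0.1; the difference between the lines was -1.11 ± 0.22, adjusted p = 0.0027. With replicate 3 as the only library of scr cells with the drug, DHODH changed by -0.03 in scr cells (adjusted p = 0.92), and the difference was -0.74 ± 0.16, adjusted p = 0.0011. FLT3, the target of the drug, was lower in shDHODH than in scr cells with DMSO (-0.54 ± 0.05, adjusted p = 1.8e-11) and rose with gilteritinib in scr cells at 96 h (0.30 ± 0.05, adjusted p = 2.5e-06), in shDHODH cells (0.32 ± 0.05, adjusted p = 1.1e-06) and in shCDK9 cells at 48 h (0.48 ± 0.15, adjusted p = 0.019). In scr cells at 48 h the FLT3 change was 0.18 ± 0.15, adjusted p = 0.36, and with replicate 3 as the only library of its group it was 0.61. The FLT3 rise in shCDK9 cells did not pass without DMSO replicate 1 (0.43) or without gilteritinib replicate 1 (0.47) or 2 (0.46), and the rises at 96 h did not pass with all 24 libraries in one model.

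**Figure D2:**
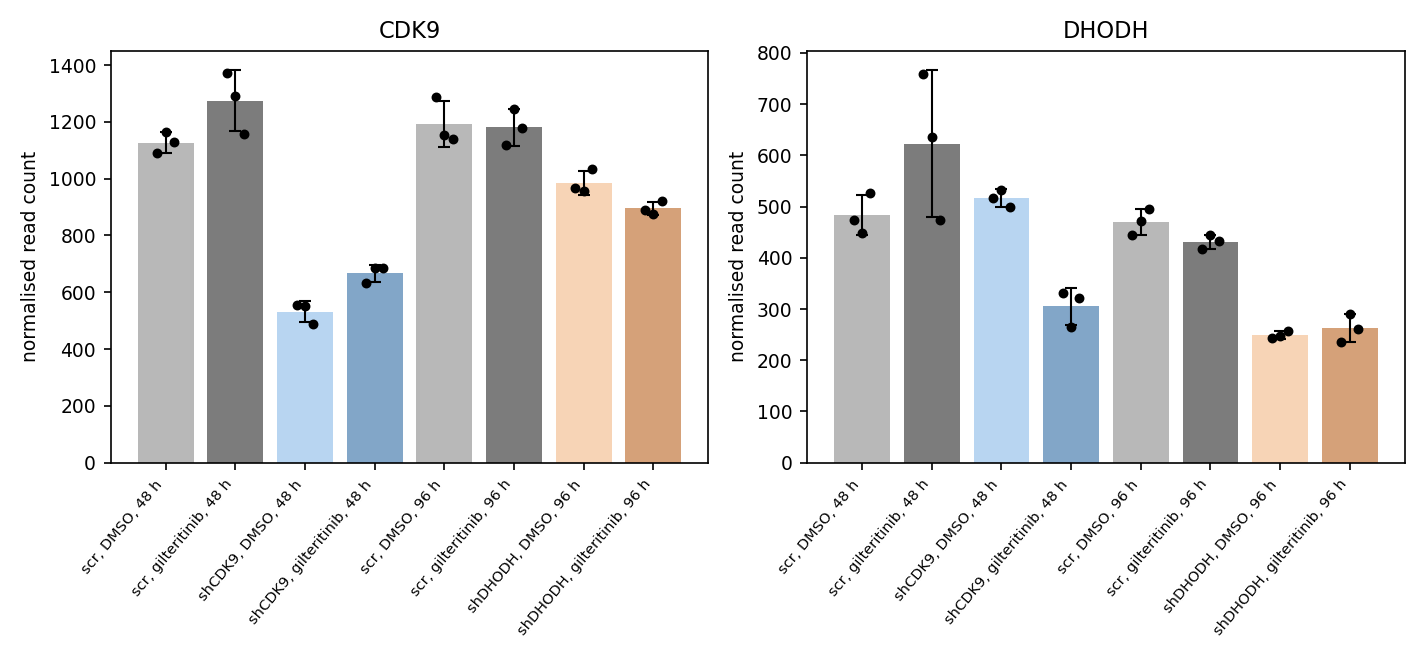
Normalised read counts of CDK9 and DHODH in the 8 groups; bars give the mean, error bars the SD and points the 3 libraries. CDK9 averaged 532 in shCDK9 and 1127 in scr cells with DMSO at 48 h, and DHODH 249 in shDHODH and 470 in scr cells with DMSO at 96 h.

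What gilteritinib did in the control line at 48 h was read from scr cells. Genes downstream of FLT3, of the ATF4 stress programme and of interferon were lower with the drug. PIM1, a serine/threonine kinase gene driven by STAT5, had a log2 fold change of -4.49 ± 0.09, adjusted p = 1.2e-10, and EGR1, an immediate early transcription factor of the MAPK pathway, -4.87 ± 0.36, adjusted p = 4.2e-06. Limma passed 5271 of 15102 genes, 2400 higher and 2871 lower, of which 1546 changed at least 2-fold. Of 31 gene lists 16 passed, 7 of them also with an estimated correlation.

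Of 14 STAT5 target genes measured 1 rose, 12 fell and 1 did not pass (1 rose and 13 fell adjusted over the list alone, median log2 -1.20, camera adjusted p = 4.1e-10), among them CISH (-2.30) and SOCS3 (-2.22), feedback inhibitors of cytokine signalling. Of 17 MAPK output genes 16 fell and 1 did not pass (16 fell adjusted over the list alone, median log2 -1.72, camera adjusted p = 1.7e-11). The ERK phosphatase DUSP6 changed by -2.39 and the Sprouty inhibitor SPRY2 by -1.94. The ATF4 response answers amino acid shortage, and of 35 genes 34 fell and 1 did not pass (34 fell adjusted over the list alone, median log2 -1.87, camera adjusted p = 1.3e-30): asparagine synthetase ASNS changed by -2.64, the mTORC1 inhibitor DDIT4 by -3.28, the pseudokinase TRIB3 by -2.62 and the secreted glycoprotein STC2 by -5.28. Of 38 interferon response genes 1 rose, 32 fell and 5 did not pass (2 rose and 33 fell adjusted over the list alone, median log2 -1.55, camera adjusted p = 4.0e-17), with the antiviral genes IFIT1 (-4.76), IFIT2 (-4.44) and HERC5 (-4.59). Of 21 NF-kB inflammatory genes 13 fell and 8 did not pass (14 fell adjusted over the list alone, median log2 -1.26, camera adjusted p = 8.8e-09). The chemokines CCL2 changed by -4.79 and CXCL8 by -2.59. Of 26 short-lived and immediate early genes 2 rose, 23 fell and 1 did not pass (2 rose and 23 fell adjusted over the list alone, median log2 -0.87, camera adjusted p = 3.3e-10). JUN changed by -2.80 and MYC by -1.67.

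Of 41 mitosis genes 27 fell and 14 did not pass (30 fell adjusted over the list alone, median log2 -0.57, camera adjusted p = 2.4e-07, adjusted p = 0.15 with an estimated correlation). The kinase PLK1 changed by -0.64 and the kinetochore gene NUF2 by -0.85. Of 13 granule genes 11 rose and 2 did not pass (11 rose adjusted over the list alone, median log2 0.86, camera adjusted p = 3.1e-05, adjusted p = 0.2 with an estimated correlation). Myeloperoxidase MPO changed by 0.79 and cathepsin G, CTSG, by 1.18. Of 10 MHC class II genes 4 rose and 6 did not pass (4 rose adjusted over the list alone, median log2 0.59, camera adjusted p = 0.0018, adjusted p = 0.15 with an estimated correlation). The invariant chain CD74 changed by 1.00. All 50 ribosomal protein genes rose (50 rose adjusted over the list alone, median log2 0.85, camera adjusted p = 1.7e-13, adjusted p = 0.45 with an estimated correlation). RPL6 changed by 0.70 and RPL11 by 1.05. Of 41 nuclear oxidative phosphorylation genes 18 rose, 1 fell and 22 did not pass (27 rose and 1 fell adjusted over the list alone, median log2 0.54, camera adjusted p = 8.5e-06, adjusted p = 0.51 with an estimated correlation). Of 13 mitochondrially encoded genes 6 rose and 7 did not pass (7 rose adjusted over the list alone, median log2 0.37, camera adjusted p = 0.014, adjusted p = 0.5 with an estimated correlation). Ribosomal protein, oxidative phosphorylation and granule genes moved with replicates 1 and 2. Their list medians against DMSO were 1.30 and 1.10 for ribosomal protein genes in these replicates and 0.17 in replicate 3, 0.95, 0.74 and -0.02 for oxidative phosphorylation, and 1.15, 1.10 and 0.29 for granule genes. Among the largest single rises were MS4A4E (2.67 ± 0.21), SIRPB2 (2.22 ± 0.18), the cannabinoid receptor CNR2 (2.03 ± 0.10) and the ubiquitin ligase DTX4 (2.10 ± 0.20), and among the largest falls the calcium-binding S100P (-5.29 ± 0.20), STC2 and OCSTAMP (-5.00 ± 0.31).

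The count was 10848 with limma voom weights, 8063 with all 24 libraries, 938 with only the 6 compared (CTSG, RPL6 and RPL11 then did not pass), 2664, 2999 and 3427 without DMSO replicates 1, 2 and 3, 2696, 2331 and 10366 without gilteritinib replicates 1, 2 and 3, and 2697 with gilteritinib replicates 1 and 2 both out. With both out, and so with replicate 3 as the only library of the group, the oxidative phosphorylation call ended (adjusted p = 0.96), RPL6 at 0.23 and RPL11 at 0.24 did not pass, CTSG passed at 0.51, the MYC and nucleolar list, at a median of 0.13 and adjusted p = 0.49 with all libraries, turned lower (adjusted p = 0.0015), and with the length trend of each library removed the mitochondrially encoded call ended (adjusted p = 0.78). Of the genes that passed 45.5% were higher, and 56.5% and 62.2% were with TMM or upper-quartile factors in edgeR.

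At 96 h the same question in the same line gave falls in the same signalling lists and a rise in the mitosis list. PIM1 changed by -4.30 ± 0.07, adjusted p = 4.8e-31, STC2 by -5.83 ± 0.16 and IFIT2 by -5.52 ± 0.18, while the scavenger receptor CD36 rose by 2.46 ± 0.13 and LYZ, lysozyme, by 2.07 ± 0.10. Limma passed 5896 of 14606 genes, 2931 higher and 2965 lower, and 825 changed at least 2-fold. Of 30 lists 17 passed, 11 of them also with an estimated correlation.

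All 35 ATF4 response genes fell (35 fell adjusted over the list alone, median log2 -1.40, camera adjusted p = 5.1e-50). DDIT4 changed by -3.26, ASNS by -2.35 and the tRNA synthetase WARS by -2.16. Of 39 interferon response genes 38 fell and 1 did not pass (38 fell adjusted over the list alone, median log2 -1.92, camera adjusted p = 9.0e-36). IFI6 changed by -4.32 and MX1 by -4.38. Of 14 STAT5 targets 1 rose, 11 fell and 2 did not pass (1 rose and 11 fell adjusted over the list alone, median log2 -1.26, camera adjusted p = 2.1e-08). CISH changed by -1.59 and the cyclin CCND2 by -1.45. Of 17 MAPK output genes 1 rose, 14 fell and 2 did not pass (1 rose and 15 fell adjusted over the list alone, median log2 -0.68, camera adjusted p = 5.2e-08). SPRY2 changed by -1.08. Of 29 glycolysis and hypoxia genes 25 fell and 4 did not pass (1 rose and 25 fell adjusted over the list alone, median log2 -0.49, camera adjusted p = 3.1e-13). VEGFA changed by -3.26 and the glucose transporter SLC2A3 by -2.22. Of 27 p53 targets 4 rose, 14 fell and 9 did not pass (4 rose and 14 fell adjusted over the list alone, median log2 -0.32, camera adjusted p = 5.3e-04). The CDK inhibitor CDKN1A changed by -1.70 and the BH3-only gene BBC3 by -0.93. Of 12 granule genes 10 rose and 2 did not pass (11 rose and 1 fell adjusted over the list alone, median log2 0.62, camera adjusted p = 3.0e-09). MPO changed by 1.17 and CTSG by 1.30. Of 41 mitosis genes 36 rose and 5 did not pass (36 rose adjusted over the list alone, median log2 0.36, camera adjusted p = 2.2e-16). CDC20 changed by 0.77 and TOP2A by 0.52.

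Of 40 S phase genes 30 rose, 2 fell and 8 did not pass (30 rose and 2 fell adjusted over the list alone, median log2 0.31, camera adjusted p = 3.2e-09, adjusted p = 0.21 with an estimated correlation). The replication clamp PCNA changed by 0.44 and the helicase subunit MCM4 by 0.43. Of 41 nuclear oxidative phosphorylation genes 33 rose and 8 did not pass (33 rose adjusted over the list alone, median log2 0.23, camera adjusted p = 4.2e-11, adjusted p = 0.13 with an estimated correlation). SDHA changed by 0.60. All 13 mitochondrially encoded genes rose (13 rose adjusted over the list alone, median log2 0.36, camera adjusted p = 1.2e-07, adjusted p = 0.15 with an estimated correlation). MT-CO1 changed by 0.34. Ribosomal protein genes did not pass as a list here (median log2 0.02, camera adjusted p = 0.79). Of 24 purine and one-carbon genes 4 rose, 15 fell and 5 did not pass (4 rose and 15 fell adjusted over the list alone, median log2 -0.21, camera adjusted p = 9.1e-07, adjusted p = 0.12 with an estimated correlation). The mitochondrial folate enzymes MTHFD2 changed by -1.40 and MTHFD1L by -1.32. MTHFD2, SHMT2, ALDH1L2, PHGDH, PSAT1 and PSPH also stand in the ATF4 response list, so this call partly repeats that one. Among the largest rises were SHISA2 (2.57 ± 0.10), B3GNT7 (2.56 ± 0.38) and MPEG1 (2.40 ± 0.14), a pore-forming protein of macrophages, and among the largest falls otoferlin, OTOF (-6.17 ± 0.33), IFIT1 (-5.98 ± 0.38) and OAS3 (-5.92 ± 0.31). With all 24 libraries in one model the count was 2946.

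Whether the response changed between 48 and 96 h was tested as the difference of both responses in scr cells, higher where the change at 96 h lay above the one at 48 h. Of 41 mitosis genes 35 were higher and 6 did not pass (35 higher adjusted over the list alone, median log2 0.96, camera adjusted p = 2.7e-26). CCNB1 differed by 0.96. Of 17 MAPK output genes 9 were higher and 8 did not pass (11 higher adjusted over the list alone, median log2 0.67, camera adjusted p = 1.3e-06). SPRY4 differed by 2.97 and EGR1 by 2.50. Of 39 interferon response genes 10 were lower and 29 did not pass (14 lower adjusted over the list alone, median log2 -0.70, camera adjusted p = 3.3e-06). MX1 differed by -1.92. Of 50 ribosomal protein genes 49 were lower and 1 did not pass (50 lower adjusted over the list alone, median log2 -0.85, camera adjusted p = 5.7e-20, adjusted p = 0.36 with an estimated correlation), a list that moved with replicates 1 and 2 of scr cells with gilteritinib at 48 h and had a median of -0.16 without them. Limma passed 2449 of 15550 genes, 1355 higher and 1094 lower. The count was 8670 with limma voom weights and 1599 with no filter; at 48 h it was 1319 without DMSO replicate 1 and 1157, 1047 and 8484 without gilteritinib replicates 1, 2 and 3, and at 96 h 1440, 1551 and 1413 without DMSO replicates 1, 2 and 3 and 1415 and 1264 without gilteritinib replicates 1 and 3. Of the genes that passed 55.3% were higher, and 30.5% were with upper-quartile factors; with replicates 1 and 2 out, which leaves 1 library for the drug at 48 h, the MYC and nucleolar, oxidative phosphorylation and granule lists, at medians of -0.18, -0.23 and -0.05 and not passing with all libraries, turned higher (adjusted p = 0.0044, 3.4e-09 and 0.0015).

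What the CDK9 hairpin line looked like without drug was read from shCDK9 against scr cells with DMSO at 48 h. Genes of mature myeloid cells and of antigen presentation were higher, and ATF4 and interferon response genes were lower. LYZ had a log2 fold change of 3.23 ± 0.11, adjusted p = 6.6e-09, MNDA, a nuclear antigen of myeloid cells, 3.05 ± 0.11, and the calcium-binding S100A9 4.48 ± 0.27. Limma passed 3486 of 15102 genes, 1847 higher and 1639 lower, and 1524 changed at least 2-fold. Of 31 lists 21 passed, 7 of them also with an estimated correlation.

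Of 43 myeloid differentiation genes 25 rose, 3 fell and 15 did not pass (27 rose and 4 fell adjusted over the list alone, median log2 1.00, camera adjusted p = 4.6e-10), among them the proteoglycan VCAN at 6.18. Of 10 MHC class II genes 9 rose and 1 did not pass (9 rose adjusted over the list alone, median log2 2.46, camera adjusted p = 3.1e-10). HLA-DRA changed by 2.46 and HLA-DRB1 by 2.77; HLA genes stand on several lines of the table, so their reads may be split between copies. Of 35 ATF4 response genes 32 fell and 3 did not pass (33 fell adjusted over the list alone, median log2 -1.05, camera adjusted p = 1.5e-22). DDIT4 changed by -2.28, TRIB3 by -1.73 and ASNS by -1.56. Of 38 interferon response genes 31 fell and 7 did not pass (1 rose and 32 fell adjusted over the list alone, median log2 -1.43, camera adjusted p = 2.8e-18). IFIT3 changed by -2.56 and MX1 by -3.02. Of 26 short-lived and immediate early genes 1 rose, 16 fell and 9 did not pass (2 rose and 19 fell adjusted over the list alone, median log2 -0.54, camera adjusted p = 1.5e-06). EGR1 changed by -2.60 and ZFP36L1, an mRNA decay factor, by -3.21. In the P-TEFb and pause release list, which holds CDK9, of 26 genes 5 fell and 21 did not pass (4 fell adjusted over the list alone, median log2 -0.04, camera adjusted p = 0.2), and it passed in none of the 13 comparisons.

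Of 13 granule genes 10 rose, 1 fell and 2 did not pass (12 rose and 1 fell adjusted over the list alone, median log2 0.95, camera adjusted p = 6.9e-05, adjusted p = 0.2 with an estimated correlation). CTSG changed by 2.12. Of 22 genes of the leukaemia stem cell programme 1 rose, 10 fell and 11 did not pass (1 rose and 11 fell adjusted over the list alone, median log2 -0.41, camera adjusted p = 0.0049, adjusted p = 0.22 with an estimated correlation). BMI1 changed by -1.74 and MEIS1 by -1.05. Of 13 mitochondrially encoded genes 10 rose and 3 did not pass (11 rose adjusted over the list alone, median log2 0.81, camera adjusted p = 8.7e-06, adjusted p = 0.18 with an estimated correlation). MT-CO1 changed by 0.90. Of 15 BCL2 family genes 1 rose, 6 fell and 8 did not pass (2 rose and 6 fell adjusted over the list alone, median log2 -0.21, camera adjusted p = 0.038, adjusted p = 0.12 with an estimated correlation): those that fell include PMAIP1 (-1.46), BMF (-0.70) and BBC3 (-0.98), which promote cell death, and BCL2A1 (-1.79), which opposes it. Of 15 fatty acid synthesis genes 5 rose, 1 fell and 9 did not pass (6 rose and 1 fell adjusted over the list alone, median log2 0.23, camera adjusted p = 0.025, adjusted p = 0.34 with an estimated correlation). The desaturases FADS2 changed by 2.32 and FADS1 by 1.99. The fibroblast markers were tested with 5 of 14 genes, and of 5 genes 3 rose and 2 did not pass (3 rose adjusted over the list alone, median log2 0.71, camera adjusted p = 0.013, adjusted p = 0.075 with an estimated correlation). ACTA2 changed by 2.17 and COL1A1 by 1.13. Among the largest single changes were rises of clusterin, CLU (6.79 ± 0.38), VCAN, the basement membrane gene NID1 (5.83 ± 0.50) and the aminopeptidase ANPEP (5.79 ± 0.24), and falls of BEX1 (-6.95 ± 0.26), ANGPT1 (-6.91 ± 0.58) and the Notch ligand JAG2 (-5.70 ± 0.27). The count was 7315 with limma voom weights, 6787 with only the 6 libraries compared and 6712 with the 2 libraries that stand apart left out of the model. The fibroblast call ended with no filter (adjusted p = 0.39) and the BCL2 family call with the length trend removed (adjusted p = 0.067).

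The shDHODH line without drug, against scr cells at 96 h, had lower ATF4 response genes. Its myeloid genes were higher and its MHC class II genes lower, calls that were lost (adjusted p = 0.11 and adjusted p = 0.099 with an estimated correlation). MNDA rose by 3.55 ± 0.10, adjusted p = 1.5e-21, the myeloid precursor gene MS4A3 by 4.01 ± 0.10, and CYBB, the catalytic subunit of the phagocyte oxidase, by 2.07 ± 0.07, while HLA-DRA, which stands on several lines, changed by -4.87 ± 0.26. Limma passed 6344 of 14606 genes, 3224 higher and 3120 lower, and 1114 changed at least 2-fold. Of 30 lists 19 passed, and with an estimated correlation 2, ATF4 and interferon response.

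Of 35 ATF4 response genes 1 rose and 34 fell (1 rose and 34 fell adjusted over the list alone, median log2 -0.65, camera adjusted p = 1.7e-23). DDIT4 changed by -1.82 and the transsulfuration enzyme CBS by -2.58. Of 39 interferon response genes 3 rose, 23 fell and 13 did not pass (3 rose and 26 fell adjusted over the list alone, median log2 -0.43, camera adjusted p = 1.5e-05). XAF1 changed by -0.78 and USP18 by -1.39. Of 40 myeloid differentiation genes 28 rose, 7 fell and 5 did not pass (30 rose and 7 fell adjusted over the list alone, median log2 0.51, camera adjusted p = 2.2e-06, adjusted p = 0.11 with an estimated correlation). TLR4 changed by 1.65 and CCR2 by 0.84. Of 12 granule genes 11 rose and 1 fell (11 rose and 1 fell adjusted over the list alone, median log2 0.97, camera adjusted p = 6.8e-08, adjusted p = 0.098 with an estimated correlation). CTSG changed by 1.02. Of 22 genes of the leukaemia stem cell programme 2 rose, 13 fell and 7 did not pass (2 rose and 15 fell adjusted over the list alone, median log2 -0.42, camera adjusted p = 3.3e-06, adjusted p = 0.11 with an estimated correlation). HOXA5 changed by -3.41, HOXA10 by -1.12 and BMI1 by -1.04. Of 7 MHC class II genes 6 fell and 1 did not pass (6 fell adjusted over the list alone, median log2 -1.98, camera adjusted p = 1.5e-05, adjusted p = 0.099 with an estimated correlation). CD74 changed by -1.13 and the transactivator CIITA by -1.98. Of 41 mitosis genes 38 rose, 1 fell and 2 did not pass (38 rose and 1 fell adjusted over the list alone, median log2 0.31, camera adjusted p = 1.3e-11, adjusted p = 0.11 with an estimated correlation). ECT2 changed by 0.62. Of 30 pyrimidine metabolism genes, the pathway of DHODH, 12 rose, 7 fell and 11 did not pass (13 rose and 7 fell adjusted over the list alone, median log2 0.13, camera adjusted p = 0.16). Of 29 glycolysis and hypoxia genes 2 rose, 21 fell and 6 did not pass (2 rose and 21 fell adjusted over the list alone, median log2 -0.43, camera adjusted p = 3.9e-09, adjusted p = 0.11 with an estimated correlation). VEGFA changed by -1.53. Of 14 STAT5 targets 3 rose, 9 fell and 2 did not pass (4 rose and 9 fell adjusted over the list alone, median log2 -0.25, camera adjusted p = 0.0076, adjusted p = 0.31 with an estimated correlation). SOCS2 changed by -2.67 and PIM1 by -1.32. Among the largest rises were WNT7B (5.60 ± 0.54), the serpin SERPINB10 (4.72 ± 0.11), the kinase ROS1 (4.60 ± 0.33) and SESN3 (4.53 ± 0.25), and among the largest falls COL8A2 (-7.30 ± 0.53), PPP1R3G (-6.71 ± 0.41), EPHB3 (-6.13 ± 0.55) and BEX1 (-5.89 ± 0.16). With all 24 libraries in one model the count was 3414.

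Gilteritinib in shCDK9 cells at 48 h, read against the drug in scr cells, shows whether lower CDK9 goes with another response. With the drug, genes of DNA replication and division fell in shCDK9 cells by far more than in scr cells. RRM2, a subunit of ribonucleotide reductase, changed by -5.00 ± 0.24, adjusted p = 1.5e-08, thymidylate synthase TYMS by -4.40 ± 0.11 and the mitotic kinase CDK1 by -4.07 ± 0.10. The difference of the responses, shCDK9 minus scr, was -4.22 ± 0.15, adjusted p = 2.3e-08, for TYMS and -3.50 ± 0.14 for CDK1. HMOX1, haem oxygenase, rose by 4.08 ± 0.18, a difference of 4.86 ± 0.25.

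**Figure D3:**
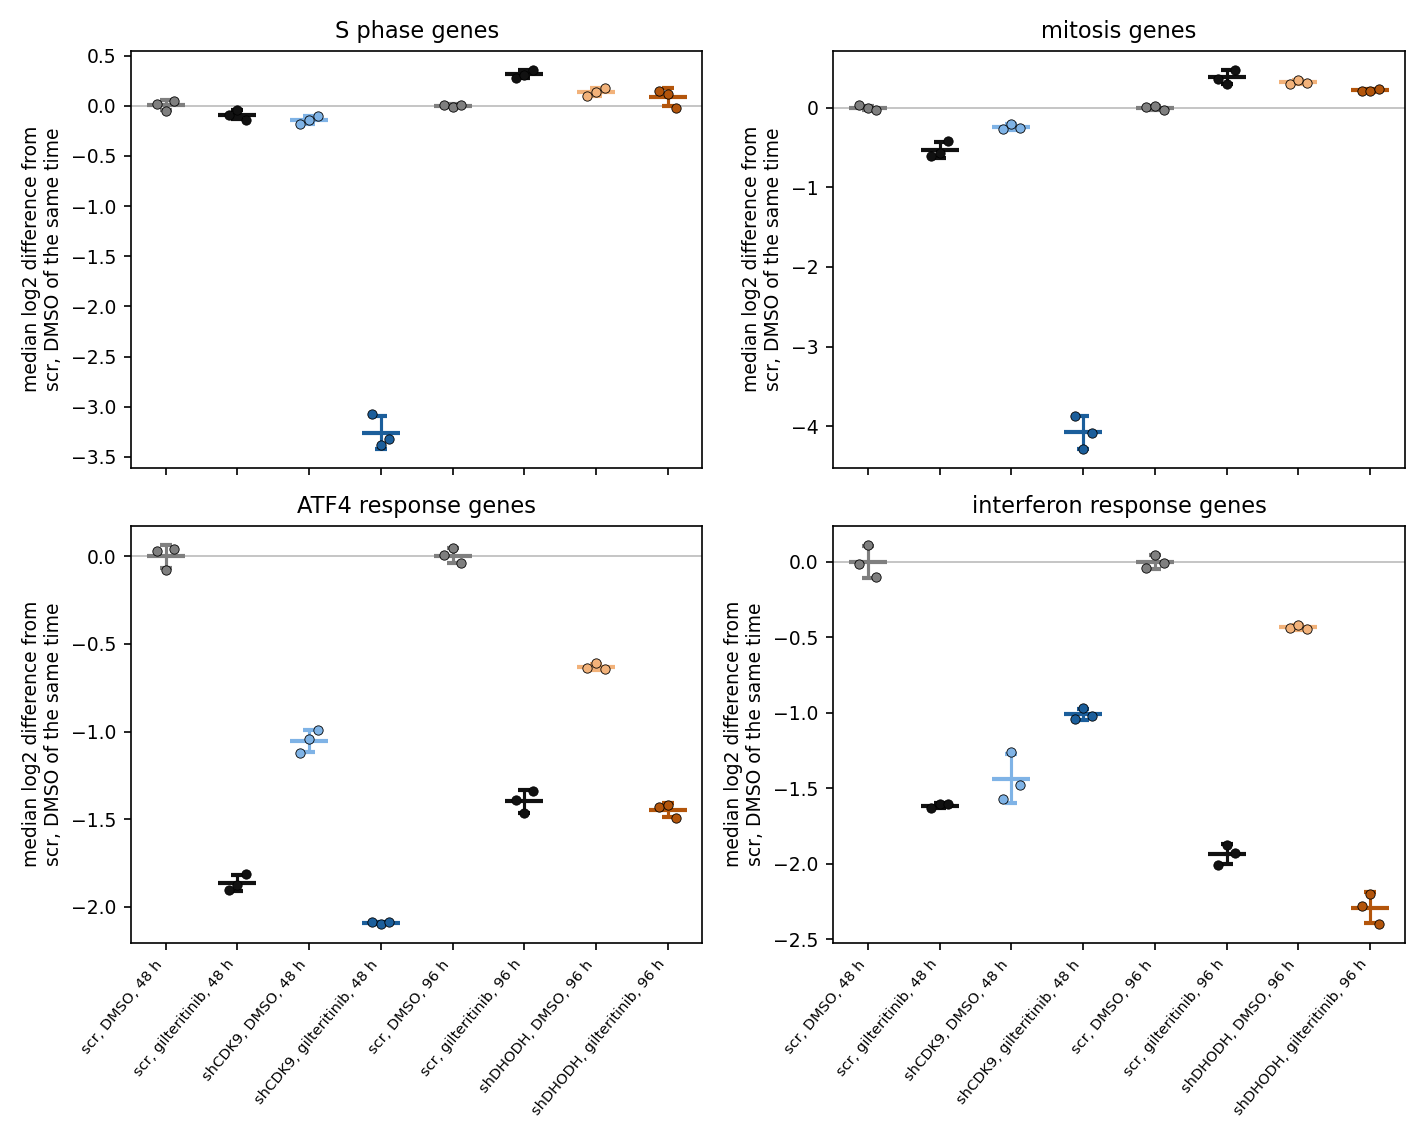
Median log2 difference of 4 gene lists from scr cells with DMSO of the same time, per library; points are the 3 libraries of a group, bars their mean and error bars the SD. S phase and mitosis genes lay far below the other groups in shCDK9 cells with gilteritinib, where the list medians against shCDK9 cells with DMSO were -3.01 and -3.84.

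For the drug in shCDK9 cells limma passed 7978 of 15102 genes, 3975 higher and 4003 lower, with 3520 changed at least 2-fold, and 18 of 31 lists passed, 9 of them also with an estimated correlation. All 40 S phase genes fell (40 fell adjusted over the list alone, median log2 -3.01, camera adjusted p = 4.4e-29). The helicase subunit MCM6 changed by -3.26. All 41 mitosis genes fell (41 fell adjusted over the list alone, median log2 -3.84, camera adjusted p = 1.1e-31). CCNB1 changed by -3.99. Of 31 pyrimidine metabolism genes 4 rose, 19 fell and 8 did not pass (4 rose and 19 fell adjusted over the list alone, median log2 -0.76, camera adjusted p = 2.0e-05). Ribonucleotide reductase RRM1 changed by -2.96. Of 25 cholesterol synthesis genes 20 fell and 5 did not pass (21 fell adjusted over the list alone, median log2 -1.21, camera adjusted p = 1.5e-09). DHCR7 changed by -2.41. Of 24 purine and one-carbon genes 21 fell and 3 did not pass (21 fell adjusted over the list alone, median log2 -1.29, camera adjusted p = 1.1e-10). Of 24 unfolded protein response genes 2 rose, 17 fell and 5 did not pass (2 rose and 17 fell adjusted over the list alone, median log2 -0.86, camera adjusted p = 4.8e-05). The disulfide isomerase PDIA4 changed by -1.40. Of 37 MYC and nucleolar genes 33 fell and 4 did not pass (34 fell adjusted over the list alone, median log2 -0.98, camera adjusted p = 2.3e-11, adjusted p = 0.065 with an estimated correlation). ODC1 changed by -1.37. Of 17 heat shock genes 14 fell and 3 did not pass (14 fell adjusted over the list alone, median log2 -1.24, camera adjusted p = 5.1e-06, adjusted p = 0.065 with an estimated correlation). HSPH1 changed by -2.16. Of 14 STAT5 targets 1 rose, 11 fell and 2 did not pass (1 rose and 11 fell adjusted over the list alone, median log2 -0.85, camera adjusted p = 5.4e-04, adjusted p = 0.065 with an estimated correlation). PIM1 changed by -3.39. Of 17 MAPK output genes 11 fell and 6 did not pass (12 fell adjusted over the list alone, median log2 -1.52, camera adjusted p = 3.5e-05). ETV4 changed by -5.04. Of 35 ATF4 response genes 4 rose, 29 fell and 2 did not pass (4 rose and 30 fell adjusted over the list alone, median log2 -1.12, camera adjusted p = 9.4e-11). PSAT1 changed by -3.99. Of 38 interferon response genes 13 rose, 5 fell and 20 did not pass (13 rose and 5 fell adjusted over the list alone, median log2 0.19, camera adjusted p = 0.086). Among the largest rises were PROC, protein C (5.59 ± 0.27), HMOX1 and COL24A1 (3.88 ± 0.38), and among the largest falls CBS (-5.14 ± 0.34), ETV4 and RRM2.

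For the difference limma passed 5388 genes, 2628 higher and 2760 lower, with 2982 at least 2-fold, and 22 lists passed, 10 of them also with an estimated correlation. All 40 S phase genes were lower (40 lower adjusted over the list alone, median log2 -2.75, camera adjusted p = 7.5e-35). All 41 mitosis genes were lower (41 lower adjusted over the list alone, median log2 -3.30, camera adjusted p = 1.2e-36). CCNB1 differed by -3.60. Of 31 pyrimidine metabolism genes 4 were higher, 16 lower and 11 did not pass (4 higher and 16 lower adjusted over the list alone, median log2 -0.58, camera adjusted p = 6.7e-05). Of 25 cholesterol synthesis genes 16 were lower and 9 did not pass (20 lower adjusted over the list alone, median log2 -1.07, camera adjusted p = 1.1e-09). DHCR7 differed by -2.09. Of 24 unfolded protein response genes 4 were higher, 13 lower and 7 did not pass (5 higher and 14 lower adjusted over the list alone, median log2 -1.01, camera adjusted p = 0.001). PDIA4 differed by -1.52. Of 38 interferon response genes 31 were higher and 7 did not pass (32 higher adjusted over the list alone, median log2 2.12, camera adjusted p = 2.0e-15). OAS1 differed by 3.92; without drug they were lower in shCDK9 than in scr cells. Of 21 NF-kB inflammatory genes 13 were higher and 8 did not pass (13 higher adjusted over the list alone, median log2 1.25, camera adjusted p = 7.1e-06). NFKB2 differed by 1.94. Of 28 p53 targets 15 were higher, 1 lower and 12 did not pass (15 higher and 1 lower adjusted over the list alone, median log2 0.73, camera adjusted p = 7.4e-05). CDKN1A differed by 1.58. Of 13 granule genes 8 were lower and 5 did not pass (8 lower adjusted over the list alone, median log2 -0.94, camera adjusted p = 0.0014, adjusted p = 0.25 with an estimated correlation). MPO differed by -2.75. Of 50 ribosomal protein genes 2 were lower and 48 did not pass (0 passed adjusted over the list alone, median log2 -0.28, camera adjusted p = 0.03, adjusted p = 0.75 with an estimated correlation). The granule and ribosomal protein lists moved with replicates 1 and 2 of scr cells with the drug. MAPK output genes differed by 0.13 in the median (camera adjusted p = 0.62). Among the largest differences were NLRP12 (4.12 ± 0.32) and the kinetochore gene SPC24 (-4.96 ± 0.29).

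With replicates 1 and 2 out, which leaves 1 library of scr cells with the drug, the granule median of the difference was -0.39 (adjusted p = 0.0497) and the ribosomal protein list turned higher, at 0.38 (adjusted p = 1.9e-05). The count for the difference was 9892 with limma voom weights and 9616 without replicate 3 of scr cells with the drug. Upper-quartile factors moved all genes by 0.14 for the drug in shCDK9 cells; of the genes passing there 49.8% were higher, and 61.1% with those factors.

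Gilteritinib in shDHODH cells at 96 h, set against scr cells, addresses the same question for DHODH. The signalling, ATF4 and interferon lists were lower with the drug as in scr cells, and lipid synthesis genes were lower too. STC2 changed by -5.53 ± 0.16, adjusted p = 1.7e-23, IFIT1 by -6.23 ± 0.38 and CBS by -4.49 ± 0.13, while CNR2 rose by 2.79 ± 0.18 and CYP1B1, a cytochrome P450, by 2.17 ± 0.07. For the drug in shDHODH cells limma passed 4855 of 14606 genes, 2151 higher and 2704 lower with 704 changed at least 2-fold, and for the difference, shDHODH minus scr, 3396, 1535 higher and 1861 lower with 416 at least 2-fold. Lists passed in 18 and 17 of 30 cases, and with an estimated correlation in 11 and 0.

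Of 14 fatty acid synthesis genes 13 fell and 1 did not pass (14 fell adjusted over the list alone, median log2 -0.89, camera adjusted p = 2.0e-16). The regulator SREBF1 changed by -1.74 and FASN by -1.01. Of 25 cholesterol synthesis genes 20 fell and 5 did not pass (20 fell adjusted over the list alone, median log2 -0.50, camera adjusted p = 2.0e-16). DHCR7 changed by -1.25. Of 41 mitosis genes 2 rose, 14 fell and 25 did not pass (2 rose and 15 fell adjusted over the list alone, median log2 -0.11, camera adjusted p = 0.021, adjusted p = 0.56 with an estimated correlation). PLK1 changed by -0.35. Of 35 genes of the ATF4 response 33 fell and 2 did not pass (33 fell adjusted over the list alone, median log2 -0.91, camera adjusted p = 8.4e-42). DDIT4 changed by -2.52. Of 39 interferon response genes 1 rose, 34 fell and 4 did not pass (1 rose and 35 fell adjusted over the list alone, median log2 -1.60, camera adjusted p = 1.0e-32). MX1 changed by -3.30. Of 17 MAPK output genes 1 rose, 13 fell and 3 did not pass (1 rose and 13 fell adjusted over the list alone, median log2 -0.63, camera adjusted p = 1.3e-05). EGR1 changed by -2.13. Of 37 MYC and nucleolar genes 1 rose, 25 fell and 11 did not pass (1 rose and 28 fell adjusted over the list alone, median log2 -0.21, camera adjusted p = 2.8e-09). MYC changed by -0.41 and nucleolin, NCL, by -0.34. Of 30 pyrimidine metabolism genes 3 rose, 9 fell and 18 did not pass (3 rose and 9 fell adjusted over the list alone, median log2 -0.08, camera adjusted p = 0.04, adjusted p = 0.39 with an estimated correlation). Uridine phosphorylase UPP1 changed by -2.88. Of 14 STAT5 targets 11 fell and 3 did not pass (11 fell adjusted over the list alone, median log2 -0.62, camera adjusted p = 5.8e-08). PIM1 changed by -2.54; with IL2RA, which had no reads with the drug, at its bound the list median was -0.42. Of 5 lymphoid markers tested 3 fell and 2 did not pass (3 fell adjusted over the list alone, median log2 -0.92, camera adjusted p = 2.7e-04), with IL7R at -3.67 and CD3D at -1.37.

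In the difference, of 14 fatty acid synthesis genes 9 were lower and 5 did not pass (1 higher and 11 lower adjusted over the list alone, median log2 -0.67, camera adjusted p = 6.3e-11, adjusted p = 0.078 with an estimated correlation). SREBF1 differed by -1.29 and FASN by -0.63. Of 25 cholesterol synthesis genes 1 was higher, 15 lower and 9 did not pass (1 higher and 15 lower adjusted over the list alone, median log2 -0.29, camera adjusted p = 7.7e-10, adjusted p = 0.18 with an estimated correlation). DHCR7 differed by -0.73. Of 41 mitosis genes 39 were lower and 2 did not pass (40 lower adjusted over the list alone, median log2 -0.46, camera adjusted p = 1.5e-25, adjusted p = 0.074 with an estimated correlation). PLK1 differed by -0.68. Of 40 S phase genes 1 was higher, 29 lower and 10 did not pass (1 higher and 33 lower adjusted over the list alone, median log2 -0.36, camera adjusted p = 4.8e-14, adjusted p = 0.18 with an estimated correlation). FEN1 differed by -0.67. Of 41 nuclear oxidative phosphorylation genes 33 were lower and 8 did not pass (34 lower adjusted over the list alone, median log2 -0.34, camera adjusted p = 3.0e-17, adjusted p = 0.11 with an estimated correlation). Of 12 granule genes 7 were lower and 5 did not pass (7 lower adjusted over the list alone, median log2 -0.49, camera adjusted p = 4.5e-07, adjusted p = 0.11 with an estimated correlation). MPO differed by -1.59. Of 35 genes of the ATF4 response 28 were higher, 1 lower and 6 did not pass (29 higher and 1 lower adjusted over the list alone, median log2 0.42, camera adjusted p = 1.1e-17, adjusted p = 0.074 with an estimated correlation). WARS differed by 1.49. Among the largest differences were rises of NLRP12 (3.37 ± 0.26) and the lysosomal nuclease DNASE2 (2.32 ± 0.16) and falls of BEX1 (-2.43 ± 0.23) and the interleukin receptor IL7R (-2.35 ± 0.22). With all 24 libraries in one model the counts were 2139 for the drug and 668 for the difference, and the differences of FASN and FEN1 did not pass. With the length trend removed, the mitosis and pyrimidine calls for the drug in shDHODH cells ended (adjusted p = 0.071 and 0.094).

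**Figure D4:**
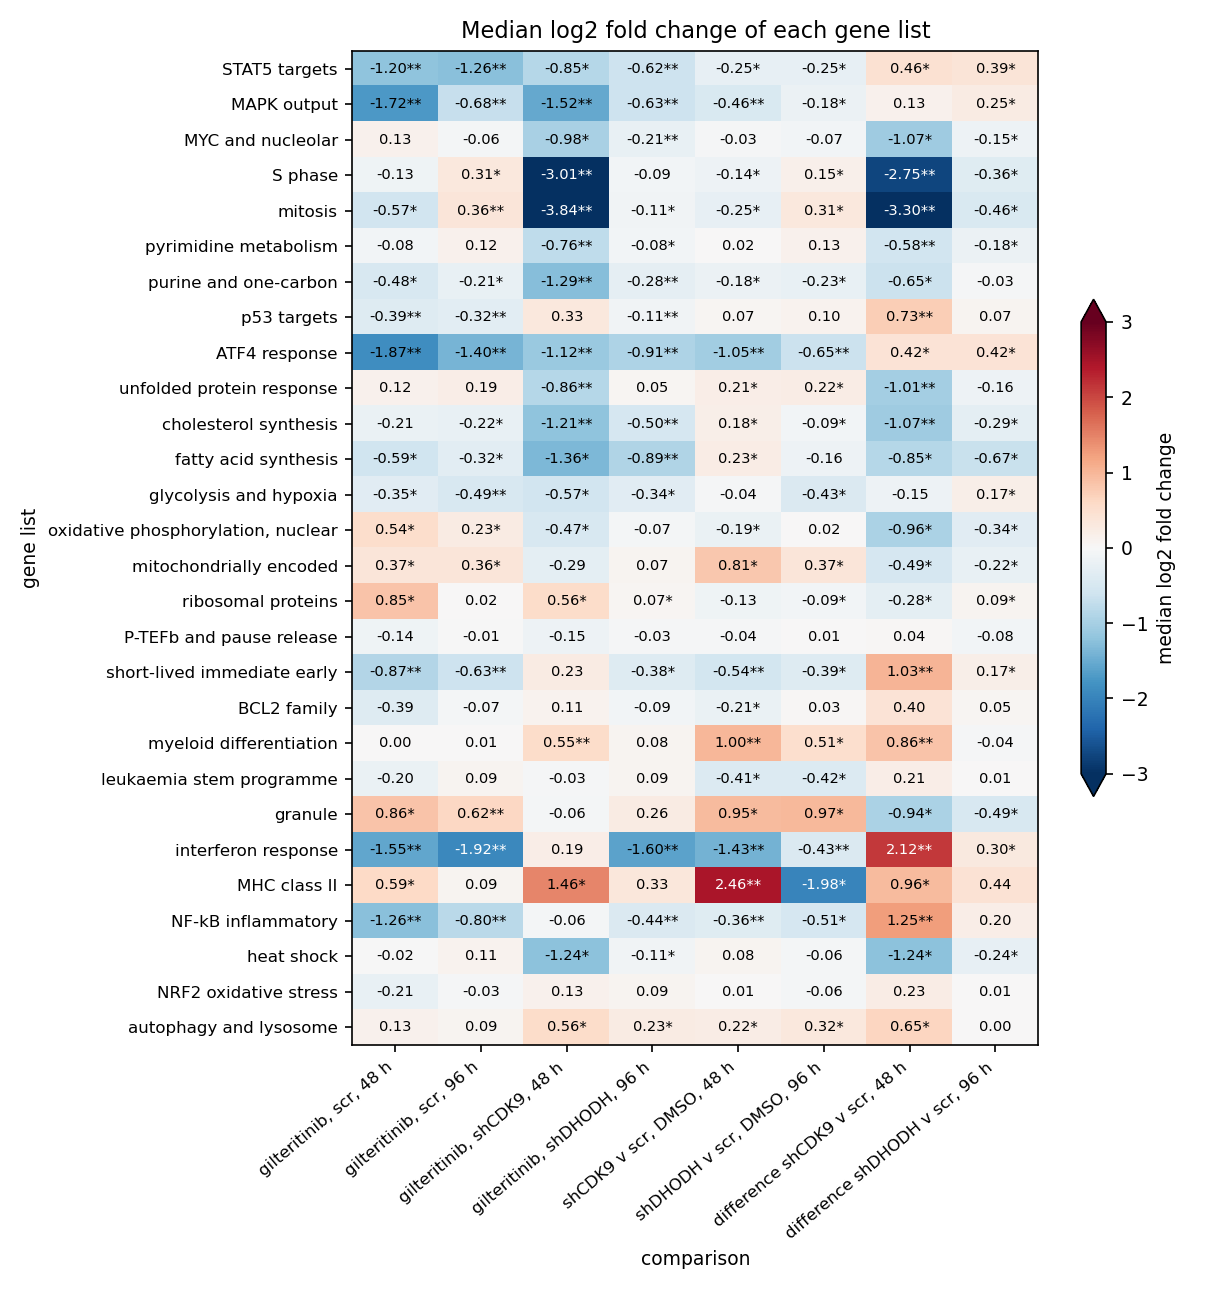
Median log2 fold change of 28 gene lists (vertical) in 8 comparisons (horizontal), where "difference" is the response of the hairpin line minus that of scr cells. One star marks a camera adjusted p under 0.05 and a pair of stars a call that also held with an estimated correlation; the S phase and mitosis medians were -3.01 and -3.84 for the drug in shCDK9 cells and -0.09 and -0.11 in shDHODH cells.

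The lines were also compared with each other under the drug. Against scr cells with gilteritinib, shCDK9 cells had lower replication and division genes and higher myeloid genes. Limma passed 9175 of 15102 genes, 4813 higher and 4362 lower, with 4684 changed at least 2-fold. All 40 S phase genes fell (40 fell adjusted over the list alone, median log2 -2.99, camera adjusted p = 2.1e-25). All 41 mitosis genes fell (41 fell adjusted over the list alone, median log2 -3.68, camera adjusted p = 6.6e-27). KIF2C changed by -4.20. Of 43 myeloid differentiation genes 38 rose, 1 fell and 4 did not pass (38 rose and 1 fell adjusted over the list alone, median log2 2.18, camera adjusted p = 7.6e-13). S100A9 changed by 5.20. Of 5 fibroblast markers tested 3 rose and 2 did not pass (3 rose adjusted over the list alone, median log2 1.06, camera adjusted p = 0.027, adjusted p = 0.1 with an estimated correlation), a call that ended with no filter (adjusted p = 0.068) and with replicates 1 and 2 of scr cells with the drug left out (adjusted p = 0.063). All 10 MHC class II genes rose (10 rose adjusted over the list alone, median log2 3.37, camera adjusted p = 2.4e-06). HLA-DRA changed by 4.02. Of 28 p53 targets 18 rose, 1 fell and 9 did not pass (18 rose and 2 fell adjusted over the list alone, median log2 0.65, camera adjusted p = 0.0016). CDKN1A changed by 1.61. Of 20 NRF2 oxidative stress genes 10 rose, 2 fell and 8 did not pass (10 rose and 2 fell adjusted over the list alone, median log2 0.41, camera adjusted p = 0.03, adjusted p = 0.21 with an estimated correlation). HMOX1 changed by 4.28. Single genes included ANPEP (7.25 ± 0.24) and BEX1 (-8.13 ± 0.26). Of 50 ribosomal protein genes 10 fell and 40 did not pass (3 fell adjusted over the list alone, median log2 -0.47, camera adjusted p = 0.003, adjusted p = 0.67 with an estimated correlation), and the list turned higher with replicates 1 and 2 of scr cells with the drug left out, which leaves 1 library there (adjusted p = 0.013).

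Against scr cells with gilteritinib at 96 h, shDHODH cells had higher myeloid and lysosomal genes, calls that were lost (adjusted p = 0.14 and adjusted p = 0.2 with an estimated correlation). Limma passed 6621 of 14606 genes, 3092 higher and 3529 lower, with 1209 changed at least 2-fold. Of 40 myeloid differentiation genes 26 rose, 3 fell and 11 did not pass (27 rose and 3 fell adjusted over the list alone, median log2 0.46, camera adjusted p = 4.8e-09, adjusted p = 0.14 with an estimated correlation). CYBB changed by 1.66. Of 29 autophagy and lysosome genes 20 rose, 4 fell and 5 did not pass (20 rose and 4 fell adjusted over the list alone, median log2 0.30, camera adjusted p = 8.0e-06, adjusted p = 0.2 with an estimated correlation). PSAP changed by 1.04. Of 22 genes of the leukaemia stem cell programme 5 rose, 14 fell and 3 did not pass (5 rose and 14 fell adjusted over the list alone, median log2 -0.65, camera adjusted p = 3.9e-05, adjusted p = 0.2 with an estimated correlation). BMI1 changed by -1.47. Of 25 cholesterol synthesis genes 21 fell and 4 did not pass (21 fell adjusted over the list alone, median log2 -0.52, camera adjusted p = 2.1e-12, adjusted p = 0.18 with an estimated correlation). HMGCS1 changed by -1.66. Of 41 nuclear oxidative phosphorylation genes 1 rose, 37 fell and 3 did not pass (1 rose and 37 fell adjusted over the list alone, median log2 -0.28, camera adjusted p = 2.1e-10, adjusted p = 0.2 with an estimated correlation). SDHA changed by -0.93. Of 5 lymphoid markers tested 4 fell and 1 did not pass (4 fell adjusted over the list alone, median log2 -1.15, camera adjusted p = 0.0025, adjusted p = 0.14 with an estimated correlation), with TRAC at -1.15. Single genes included WNT7B (6.04 ± 0.54) and BEX1 (-8.32 ± 0.16). The count was 3564 with all 24 libraries in one model.

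Responses were set side by side across genes, where genes are not independent replicates and no library is shared. The drug response in scr cells at 48 h and in shCDK9 cells had r = 0.383, with 1207 genes higher and 1316 lower in both, 552 in opposite directions, and 632 and 761 shared by chance from the counts. In scr and shDHODH cells at 96 h r was 0.655, with 952 higher and 1452 lower in both and 383 opposite. Within scr cells, 48 h against 96 h gave 0.646, with 1039 and 1518 shared and 241 opposite, and the responses of the hairpin lines gave 0.366. The changes of shCDK9 and shDHODH lines against scr cells with DMSO had r = 0.419, with 792 higher and 878 lower in both, 395 opposite and 359 and 348 shared by chance. These r are Pearson values. Spearman rho was 0.362 for the drug in scr and shCDK9 cells and 0.409 in scr and shDHODH cells. It was 0.464 within scr cells, 0.451 for the drug in both hairpin lines and 0.347 for the hairpin lines with DMSO. By rank, the drug responses of the hairpin lines were thus not the least alike.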

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

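In this part the tests chosen only after the data or the result were seen were those on gene length in the 2 libraries that stand apart, for a part and for the whole of their difference, each value with these libraries left out, and each value with the length trend removed. The list medians per library were also added then. Results stand here where a test of the difference between 2 responses passed (limma and camera, Benjamini-Hochberg). Between shCDK9 and scr cells at 48 h the response to gilteritinib differed for 5388 genes. By list, the median log2 differences were -2.75 for S phase, -3.30 for mitosis, -0.58 for pyrimidine metabolism, -1.07 for cholesterol synthesis, -1.01 for the unfolded protein response, -0.94 for granule genes and -0.28 for ribosomal proteins. The last 2 calls were lost (adjusted p = 0.25 and adjusted p = 0.75 with an estimated correlation), and both lists moved with replicates 1 and 2 of scr cells with the drug. With replicate 3 as the only library of that group the granule median was -0.39 (adjusted p = 0.0497) and the ribosomal list was higher, at 0.38 (adjusted p = 1.9e-05). List medians were above 0 for interferon response (2.12), NF-kB (1.25) and p53 targets (0.73). Single genes were SPC24 (-4.96), TYMS (-4.22), CCNB1 (-3.60), CDK1 (-3.50), MPO (-2.75), DHCR7 (-2.09), PDIA4 (-1.52), DHODH (-1.11, and -0.74 with replicate 3 alone), HMOX1 (4.86), NLRP12 (4.12), OAS1 (3.92), NFKB2 (1.94) and CDKN1A (1.58).

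Between shDHODH and scr cells at 96 h the response differed for 3396 genes. The list medians were -0.67 for fatty acid synthesis, -0.29 for cholesterol synthesis, -0.46 for mitosis, -0.36 for S phase, -0.34 for nuclear oxidative phosphorylation, -0.49 for granule genes and 0.42 for the ATF4 response. None of these calls held with an estimated correlation, with in the same order adjusted p = 0.078, 0.18, 0.074, 0.18, 0.11, 0.11 and 0.074. The ATF4 difference goes with lower levels in shDHODH cells with DMSO and not with higher levels under the drug. Single genes were BEX1 (-2.43), IL7R (-2.35), MPO (-1.59), SREBF1 (-1.29), DHCR7 (-0.73), PLK1 (-0.68), FEN1 (-0.67), FASN (-0.63), NLRP12 (3.37), DNASE2 (2.32) and WARS (1.49). Between 96 h and 48 h the response of scr cells differed for 2449 genes. The list medians were 0.96 for mitosis, 0.67 for MAPK output, -0.70 for interferon response and -0.85 for ribosomal proteins. The ribosomal call was lost (adjusted p = 0.36 with an estimated correlation) and went with replicates 1 and 2 of the drug at 48 h, with list medians against DMSO of 1.30 and 1.10 and 0.17 in replicate 3. Single genes were SPRY4 (2.97), EGR1 (2.50), CCNB1 (0.96) and MX1 (-1.92).

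The counts were also made for other splits of the same libraries. For the difference between shDHODH and scr cells 2 of 100 splits drawn gave as many genes, the real one (3396) included; the other exchanged all 3 gilteritinib labels between the lines and gave 7477. For shCDK9 and scr cells it was 6 of 100, the real one (5388) included, with 6152 as the highest other; the 5 others exchanged 3 gilteritinib labels and 1 DMSO label, or 2 DMSO labels. In both comparisons the splits exchange labels between the lines, so they carry the effects of line and drug and are no measure of chance alone, and neither share excludes chance. Against chance for the cell cycle genes, S phase medians relative to scr cells with DMSO were -3.07, -3.38 and -3.32 in the libraries of shCDK9 cells with gilteritinib and -0.18 to 0.05 in the other 9 at 48 h. For the comparison of times it was 9 of 100, the real one included, which does not exclude chance either. Its highest split gave 7361 against the real 2449, with all 3 gilteritinib labels exchanged between the times. That exchange turns the contrast into the difference between the times summed over both treatments. These splits thus carry the effect of time and are no measure of chance alone. The other 10 comparisons are of 3 against 3 libraries, and their 10 splits are too few for a share under 0.05; the real split was the only 1 of the 10 to give as many genes in each. The highest other split was 4025 for gilteritinib in scr cells at 48 h, against 5271. It was 0 for gilteritinib in scr cells at 96 h (5896), in shCDK9 (7978) and in shDHODH cells (4855), for shCDK9 with DMSO (3486) and with gilteritinib (9175), for shDHODH with DMSO (6344) and with gilteritinib (6621), and for drug and hairpin together (9111 and 8087).

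A first pattern is that replicates 1 and 2 of scr cells with gilteritinib at 48 h stood apart from replicate 3. A swap with shCDK9 cells or with untreated cells is argued against. The higher of the 2 lay at 0.157 on the axis from scr to shCDK9 cells, and the lower slope on the 96 h drug response was 0.818. Replicate 3 had 0.163 and 0.805, so these values do not separate the replicates, and other swaps were not tested. A few abundant genes are also argued against. Without ribosomal protein and top genes the SD of the difference across genes was 0.808 (0.355 at most in other groups). The difference fell with gene length (Spearman rho -0.453, at most 0.343 in size in other groups), from a median of 0.595 in the fifth with the shortest genes to -0.502 in the fifth with the longest. This suggests that a length bias, as RNA quality or library preparation could give, was part of it, but not the whole, since with the length trend removed the SD stayed at 0.703 (0.779 before, 0.311 at most in other groups). GC content cannot be told apart, with rho 0.389 against 0.398 in another group, and no biological explanation was tested.

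The second pattern is the fall of S phase and mitosis genes with gilteritinib in shCDK9 cells beyond that in scr cells. Over the 81 genes the median difference was -3.20. With the 2 libraries that stand apart left out, which leaves 1 library in their group, it was -3.39 (SE 0.169). With the length trend removed it was -3.20. These values argue against each of these as the source. Nearest to 0 over 3 other scalings the median was -3.13. Such scalings move all genes together, here by at most 0.073 with upper-quartile factors, so they could not have removed the fall. They do not address a change shared by most genes. A candidate explanation is that lower CDK9 and FLT3 inhibition together halt the cell cycle; a property of this line other than the knockdown stays open, since there was 1 hairpin per gene and it was not tested.

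The third pattern is that shCDK9 and shDHODH lines shared changes against scr cells, with r = 0.419 across genes. With the length trend removed r was 0.425 over 12575 genes, which argues against gene length as the source. Among 6180 genes that did not pass for gilteritinib in scr cells it was 0.411, so it does not rest only on genes that passed. Genes that respond without passing stay among them, so an overlap with the drug response stays open. On the 96 h drug response, over genes it changed at least 2-fold, shCDK9 libraries with DMSO had slopes of 0.475 to 0.495. A change in the scrambled line itself cannot be told apart, since no library without a hairpin was in the groups: 428 genes changed at least 2-fold the same way in both lines and 81 in opposite ways. A common effect of lowering either gene could also give this and was not tested.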

How the results depend on the processing

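Alternatives chosen only after the data were seen, and so tests of that kind, were TMM factors in limma, another constant added before the log, only names with 1 line, the length trend removed, replicates 1 and 2 of scr cells with gilteritinib at 48 h left out, and the left-out libraries for the correlations. EdgeR with TMM factors was the planned test and became an alternative once the unit was known. The CDK9 and DHODH knockdown kept its direction and passed under each alternative run: without each library in turn CDK9 was -1.11 to -1.02 with DMSO and -0.996 to -0.874 with gilteritinib, and DHODH -0.95 to -0.87 and -0.80 to -0.65. Of 294 alternative counts of passing genes 263 lay within 1.5 times the reported count. For gilteritinib in shCDK9 cells, shCDK9 with gilteritinib, and drug and hairpin together in each line, all did. No named gene passed with its sign reversed. With replicate block in the model, shCDK9 with DMSO gave 3049 genes and the difference between shCDK9 and scr cells 4738, and no count moved by over 1.5 times; the numbers do not pair the samples.

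With limma voom weights the counts were 10848 for gilteritinib in scr cells at 48 h, 7315 for shCDK9 with DMSO, 9892 for the difference between shCDK9 and scr cells and 8670 for the comparison of times. With all 24 libraries in one model they were 8063 for gilteritinib in scr cells at 48 h and 2946 at 96 h, 3414 for shDHODH with DMSO, 2139 for gilteritinib in shDHODH cells, 3564 for shDHODH with gilteritinib and 668 for the difference between shDHODH and scr cells. That model shares 1 variance per gene over both times, so the spread of scr cells with gilteritinib at 48 h enters the tests at 96 h. With only the 6 libraries compared, which leaves fewer degrees of freedom and takes the spread of other groups out of the variance, gilteritinib in scr cells at 48 h gave 938 and shCDK9 with DMSO 6787. With replicates 1 and 2 of scr cells with gilteritinib at 48 h out, so that 1 library stands for that group, these were 2697 and 6712. No filter gave 1599 for the comparison of times, and more genes tested share the adjustment. The other causes were not tested.

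Without each library in turn, gilteritinib in scr cells at 48 h gave 2331 to 10366: at 48 h 2664, 2999 and 3427 without DMSO replicates 1, 2 and 3, and 2696, 2331 and 10366 without gilteritinib replicates 1, 2 and 3. The comparison of times gave 1047 to 8484: at 48 h 1319 without DMSO replicate 1 and 1157, 1047 and 8484 without gilteritinib replicates 1, 2 and 3, and at 96 h 1440, 1551 and 1413 without DMSO replicates 1, 2 and 3 and 1415 and 1264 without gilteritinib replicates 1 and 3. The difference between shCDK9 and scr cells gave 4240 to 9616, the highest without gilteritinib replicate 3 of scr cells. A group left with 2 libraries, or 1, is assumed to vary like the others. Ranges in the other comparisons were 5197 to 5611 for gilteritinib in scr cells at 96 h, 2615 to 2890 and 5520 to 5728 for shCDK9 and shDHODH with DMSO, 4103 to 4355 for gilteritinib in shDHODH cells and 2770 to 3518 for the difference between shDHODH and scr cells.

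Some correlations across genes moved by more than the spread with the gene set. Among genes with a mean CPM of at least 5, r was 0.326 for the drug in scr and shCDK9 cells, 0.693 in scr and shDHODH cells and 0.393 for the hairpin lines with DMSO. With the 2 libraries out r was 0.688 for the drug in scr cells at 48 and 96 h, inside its range with single libraries left out. Without each library in turn the ranges were 0.333 to 0.406, 0.622 to 0.658, 0.405 to 0.418 and 0.547 to 0.703, in that order, and 0.345 to 0.374 for the drug in both hairpin lines; why was not tested.

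Among lists, 6 turned direction with replicates 1 and 2 of scr cells with gilteritinib at 48 h out, which leaves 1 library in that group: MYC and nucleolar genes for the drug in scr cells (adjusted p = 0.0015), ribosomal proteins for shCDK9 with gilteritinib (adjusted p = 0.013) and for the difference between shCDK9 and scr cells (adjusted p = 1.9e-05), and MYC and nucleolar, oxidative phosphorylation and granule genes for the comparison of times (adjusted p = 0.0044, 3.4e-09 and 0.0015); the cause was not tested. Fry did not pass ribosomal proteins in the 2 shCDK9 comparisons named (adjusted p = 0.14 and 0.45) and passed the P-TEFb list for shCDK9 with DMSO (adjusted p = 0.0015). The depth of 14.3 M to 20.1 M reads leaves genes with few reads below the filter, and at 48 h the spread in scr cells with gilteritinib limits small changes. In the simulation of that comparison 6% of changes of log2 0.5 in 14709 genes were recovered. There few genes changed and the spread was the same in all groups, so this is not the share recovered in the data.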

Other observations

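None of the tests in this part was chosen only after its result was seen. An exception is a median without replicates 1 and 2 of scr cells with gilteritinib at 48 h, added later. Cells with hairpin and drug were also compared with scr cells that had neither. In shCDK9 cells with gilteritinib, mature myeloid genes were far higher and replication genes far lower: the calcium-binding S100A8 changed by 6.27 ± 0.28, adjusted p = 5.7e-09 (limma, Benjamini-Hochberg), S100A9 by 5.95 ± 0.27, LYZ by 3.46 ± 0.11 and STC2 by -7.37 ± 0.23. Of 43 myeloid differentiation genes 32 rose, 3 fell and 8 did not pass (32 rose and 3 fell adjusted over the list alone, median log2 1.48, camera adjusted p = 3.6e-09). All 10 MHC class II genes rose (10 rose adjusted over the list alone, median log2 4.35, camera adjusted p = 4.6e-07). All 40 S phase genes fell (40 fell adjusted over the list alone, median log2 -3.23, camera adjusted p = 5.4e-24). Of 35 genes of the ATF4 response 31 fell and 4 did not pass (1 rose and 31 fell adjusted over the list alone, median log2 -2.10, camera adjusted p = 2.9e-16). Limma passed 9111 of 15102 genes, 4575 higher and 4536 lower, with 4759 changed at least 2-fold; upper-quartile factors moved all genes by 0.16. In shDHODH cells with gilteritinib SERPINB10 changed by 6.59 ± 0.11, adjusted p = 5.3e-30, WNT7B by 6.45 ± 0.54, STC2 by -7.76 ± 0.16 and CBS by -7.07 ± 0.13. Of 35 ATF4 response genes 34 fell and 1 did not pass (34 fell adjusted over the list alone, median log2 -1.41, camera adjusted p = 7.0e-32). Of 39 interferon response genes 1 rose and 38 fell (1 rose and 38 fell adjusted over the list alone, median log2 -2.27, camera adjusted p = 6.1e-23). Of 25 cholesterol synthesis genes 23 fell and 2 did not pass (23 fell adjusted over the list alone, median log2 -0.62, camera adjusted p = 1.3e-11, adjusted p = 0.094 with an estimated correlation). Of 5 lymphoid markers tested 4 fell and 1 did not pass (4 fell adjusted over the list alone, median log2 -2.04, camera adjusted p = 3.6e-04), with CD3D at -2.04. Limma passed 8087 of 14606 genes, 4027 higher and 4060 lower, with 1802 changed at least 2-fold.

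Markers of other cell types were mostly below the filter. The lymphoid list had 5 of 18 genes tested at 96 h, and for gilteritinib in scr cells, of 5 genes 4 fell and 1 did not pass (4 fell adjusted over the list alone, median log2 -1.07, camera adjusted p = 0.005); results for the other comparisons at 96 h in which it passed stand with them. The erythroid and megakaryocyte list had 5 of 18 genes tested at 48 h, none of which passed for gilteritinib in scr cells (median log2 0.65, camera adjusted p = 0.55). With replicate 3 as the only library of scr cells with the drug its median was -0.002. The epithelial list had too few genes above the filter to be tested.

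P-TEFb releases paused polymerase into the gene body. A hypothesis written down before its test was that transcripts of long genes fall more when CDK9 is lowered. In shCDK9 cells with DMSO the log2 change had a Spearman rho of 0.0308 with the genomic span across genes, and -0.0078 within the middle part of exon lengths. Both lie near 0, against the hypothesis for transcript levels at this level of CDK9. The rate of transcription was not measured.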
